A study of Mus musculus with 2 samples.

How the data were processed

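Total RNA was sequenced after ribosomal RNA depletion from the nucleoplasmic fraction of mouse bone-marrow-derived macrophages, which are macrophages grown from marrow precursors. The cells of strain C57BL/6J had been stimulated with lipid A, the part of bacterial lipopolysaccharide that activates the receptor TLR4, at 100 ng/ml for 90 min. The labels give 1 group with 2 biological replicates, both tied to the same donor entry, so the spread between them may be partly technical. Starting RNA was 1 µg in replicate 1 and 500 ng in replicate 2, per the labels, with a size range of 250 to 400 in both.

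For each library, the authors deposited a gene table and a transcript table from 1 quantification and a second transcript table from another. Per the file headers and the accompanying notes, the first quantification started from a transcriptome alignment to mm10 with GENCODE release M21, and the second was made directly from 10 read files per library. The aligner and the quantifiers are not given in the sources used here. The deposited estimated counts are unnormalized read numbers that need not be whole. The deposited TPM values are relative transcript abundances that sum to the same total in each library, over all features, small RNAs included. The deposited FPKM values are scaled to transcript length and library size and served only as an alternative. The percent of a gene's expression per isoform, deposited by the authors, was not used for any printed value. The deposited interval bounds of TPM (unit signal) are printed for a few single genes that differed between the libraries. These bounds were not used for any other printed value. Gene types, transcript types and coordinates came from the GENCODE M21 annotation of the same assembly, in which all 55536 annotated gene identifiers of the files were found.

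The first quantification held 22669533 estimated counts in replicate 1 and 14939143 in replicate 2. A gene at 1 TPM had a median of 55 and 24 counts. A count of 0 allows up to 3 counts, which is a CPM of 0.132 and 0.201. Features with an effective length under 200 took 73.9% and 57.0% of all TPM, so the TPM of longer genes were compressed by different amounts. The median log2 ratio of TPM, replicate 2 over replicate 1, was 0.38 over 8560 protein-coding genes, and all ratios below are relative to such a median. Intervals of shares and floors of counts cover counting error only, since no molecular identifiers are named in the sources used here.

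Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. With 1 group and no unstimulated or cytoplasmic library, no test between conditions was made and no p-value is given. Levels were set against other genes of the same libraries. For each of 25 gene lists with 510 genes, written before the data were examined, the median TPM was compared with 10000 random lists of the same size. Those lists came from protein-coding genes at 1 TPM or more in both libraries. Of the 510 genes, 505 were measured. Where several genes shared a symbol, the gene with the highest mean TPM was taken.

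The difference between the libraries was the median log2 ratio of TPM + 0.1 over members with a mean of 1 TPM or more, for lists with at least 3 such members. It was set against random lists matched on the decile of mean TPM, and a list outside their central 95% is described as outside. The retained-intron share was the percent of a gene's TPM given to transcripts annotated as retained intron, for protein-coding genes with such a transcript and a protein-coding transcript. Lists needed 5 such genes. Random lists describe these libraries and assume independent genes, which coregulated genes are not. The spread between the libraries was the biological coefficient of variation from edgeR's common dispersion of an intercept-only fit, on counts rounded to whole numbers, after filterByExpr and TMM scaling. Ratios of single genes used TMM-scaled counts with a prior count of 2.

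The dispersion was tested on simulated data. Simulated values of 0.1, 0.2 and 0.4 without changed genes came back as 0.100, 0.199 and 0.389, and with 200 genes changed 4-fold as 0.157, 0.231 and 0.406. In 10 simulations of the list comparison over 9006 genes, a mean of 4.7% of 200 unchanged lists of 25 genes fell outside (range 2% to 8.5%). Of 40 lists of 5 genes shifted by -1 on the log2 scale, a mean of 96.2% did (range 87.5% to 100%).

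Named genes followed a rule written before the data were examined. It took the 3 members with the highest mean TPM of each list, and the 5 highest and 2 lowest of the 5 response lists. It added the 10 most abundant protein-coding genes outside the mitochondrial genome and the 5 most abundant long noncoding genes, each with an effective length of 200 or more. It also took the 5 genes higher and 5 lower in replicate 2 with a mean count of 200 or more, and the 3 highest retained-intron shares in each list above percentile 97.5. Predicted genes and pseudogenes were counted without being named, except among the genes that differed between the libraries and for Cxcl11, a polymorphic pseudogene in the interferon list. Other names were chosen after their values were seen, which is stated beside them.

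Alternatives covered the detection threshold (0.5 TPM, 5 TPM or 10 counts), scaling (DESeq2 size factors, library size), count filters, pseudocounts (0.01 and 1), TPM rescaled to protein-coding genes, FPKM, the second quantification, other reference sets and each library alone. A correction for GC content and transcript length, and other scalings of the count of genes beyond 2-fold, were added after seeing the data. Near-identical copies (Rn7s1 and Rn7s2, Lilr4b and Lilrb4a, nuclear copies of mitochondrial genes, histone and small nuclear RNA copies), overlapping genes and antisense genes are uncertain, since how reads were split is not given in the sources used here.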

Results

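The series held 2 ribosomal-RNA-depleted libraries of nucleoplasmic RNA from bone-marrow-derived macrophages of C57BL/6J mice after 90 min with 100 ng/ml lipid A. Replicate 1 had 22669533 estimated counts and replicate 2 had 14939143. At 1 TPM or more in both libraries, 10692 annotated genes were detected, among them 8560 protein-coding, 1448 long noncoding, 542 pseudogenes and 127 small noncoding genes. The data describe which transcripts were present in the nucleoplasmic fraction at this time point. The purity of the fraction was not measured here. Values are means ± SD over both libraries (n = 2) unless a library is named. The SDs of TPM are of deposited values and include the shift of 0.38 in median log2 ratio between the libraries. They do not measure the difference of a gene relative to other genes. Thus Gbp5, at 455 ± 3.56 TPM, was 1.37-fold lower in replicate 2 by TMM-scaled counts, while Psap, at 2504 ± 517 TPM, was 1.01-fold higher.

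Outside the mitochondrial genome and among genes with an effective length of 200 or more, the most abundant protein-coding transcripts included those of lysosomal, myeloid receptor and antigen presentation genes. Psap, the precursor of the saposins that activate lysosomal lipid breakdown, stood at 2504 ± 517 TPM, on chromosome 10 at 60277627 to 60302597 (mm10). The myeloid receptor genes Lilr4b (2279 ± 409 TPM) and Lilrb4a (2186 ± 273 TPM) followed, and as near-identical neighbours they may share reads. Gpnmb, a membrane glycoprotein of macrophages, reached 1738 ± 489 TPM, and Tnfaip2, a TNF-inducible gene, 1290 ± 418 TPM. The cathepsin protease genes Ctsb (1288 ± 384 TPM) and Ctsd (1049 ± 252 TPM), the class I antigen-presenting gene H2-K1 (1073 ± 176 TPM) and the lysozyme gene Lyz2 (1010 ± 133 TPM) were at similar levels. Malt1, whose product links receptors to NF-kB, stood at 890 ± 323 TPM. The median over expressed protein-coding genes was 7.72 TPM.

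Among long noncoding RNAs, Malat1 (chromosome 19, 5795690 to 5802672) took 11.3% ± 0.33 of all estimated counts. Its TPM differed far more, with 13906 in replicate 1 and 31665 in replicate 2, while its share of counts was 11.5% and 11.1%. TPM divides counts by effective length, which for Malat1 was 5392 in replicate 1 and 3026 in replicate 2. By TMM-scaled counts Malat1 was only 1.04-fold lower in replicate 2, so its TPM does not show a doubling of the RNA. Neat1, the scaffold of nuclear paraspeckles, stood at 889 ± 27.0 TPM. Mir155hg, the host of microRNA 155, stood at 433 ± 82.8 TPM. The other 2 of the 5 most abundant long noncoding genes had predicted-gene symbols. Xist, the RNA that coats the inactive X chromosome, took 0.806% ± 0.0214 of counts.

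Protein-coding genes received 65.6% of estimated counts in replicate 1 and 63.3% in replicate 2, and long noncoding genes 17.4% and 17.0%. Mitochondrial RNA and small noncoding RNA differed more between the libraries. Genes of the mitochondrial genome held 4.92% in replicate 1 (Wilson 95% interval 4.91% to 4.93%) and 12.1% in replicate 2 (12.10% to 12.13%), a ratio of 2.46. The cytochrome oxidase gene mt-Co1 alone held 2.15% and 4.77%. Small noncoding genes held 9.02% and 3.34%. Among them Rn7sk, the RNA that restrains the elongation factor P-TEFb, held 5.47% and 1.52%. Rpph1, the RNA of ribonuclease P, held 1.24% and 0.389%. Pseudogenes held 1.93% and 3.87%.

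**Figure D1:**
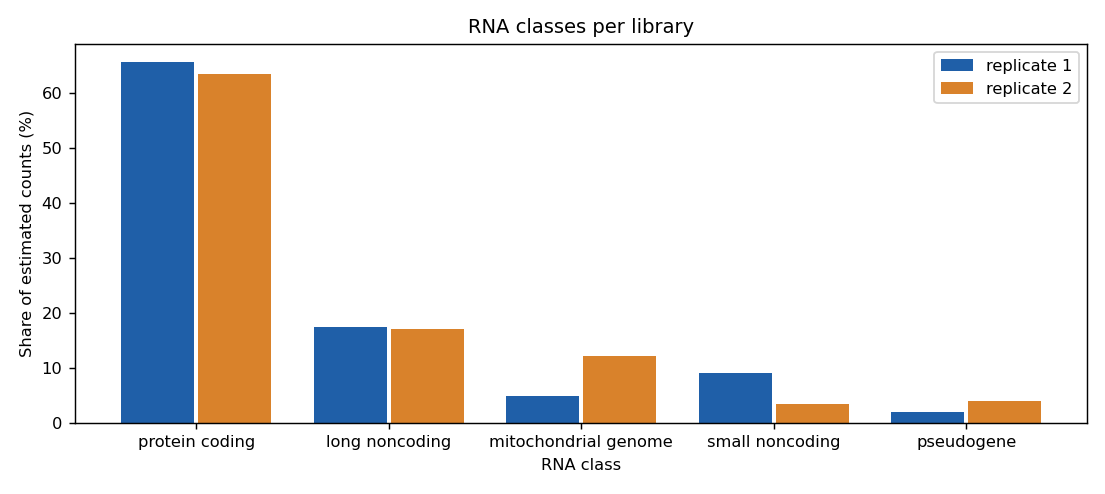
Share of estimated counts (%, vertical axis) in each RNA class (horizontal axis) for replicate 1 and replicate 2, 1 bar per library. Protein-coding and long noncoding shares were close, while mitochondrial RNA was 4.92% and 12.1% and small noncoding RNA 9.02% and 3.34%.

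Which parts of the lipid A response were present in nucleoplasmic RNA was read from 5 response lists. Cytokines and chemokines, interferon response genes and NF-kB feedback genes were abundant in both libraries. The list of inflammatory cytokines and chemokines had a median of 87.3 ± 9.96 TPM, with 23 of 24 genes at 1 TPM or more in both libraries and 11 at 100 TPM or more. Its highest members were the chemokine genes Ccl4 (507 ± 185 TPM), Ccl3 (431 ± 42.3 TPM) and Ccl2 (378 ± 86.5 TPM), with Tnf (402 ± 8.03 TPM) and Tnfsf9 (385 ± 11.0 TPM). The lowest were the neutrophil chemokine gene Cxcl3 (2.77 ± 0.424 TPM) and the granulocyte growth factor gene Csf3 (0.275 ± 0.290 TPM, 3 and 10 counts). The NF-kB feedback list had a median of 75.1 ± 2.31 TPM, and 17 of its 18 genes were at 10 TPM or more in both libraries. Tnip3 (857 ± 116 TPM), the ubiquitin editor Tnfaip3 (605 ± 107 TPM), the NF-kB inhibitor Nfkbia (372 ± 95.1 TPM), the subunit gene Nfkb1 (275 ± 81.9 TPM) and Nfkbiz (158 ± 16.9 TPM) led it. Nfkbib (26.1 ± 1.77 TPM) and the deubiquitinase gene Cyld (13.8 ± 5.90 TPM) were lowest.

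The interferon response list had a median of 88.2 ± 12.4 TPM, and 27 of its 28 genes were at 1 TPM or more in both libraries. Antiviral genes led it: Rsad2, which encodes viperin, stood at 657 ± 231 TPM, the chemokine gene Ccl5 at 559 ± 186 TPM and the guanylate-binding protein gene Gbp5 at 455 ± 3.56 TPM. Oasl2 (433 ± 16.3 TPM) and the RNA sensor gene Ifih1 (429 ± 33.5 TPM) followed. Cxcl11 (3.26 ± 2.22 TPM), annotated as a polymorphic pseudogene, and the T cell chemokine gene Cxcl9 (0.690 ± 0.0283 TPM) were lowest, with 66 and 6 counts for Cxcl9. These 3 lists lay above each of 10000 random lists of expressed protein-coding genes (percentile 100), in each library alone as well.

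By their medians, immediate-early genes and late response genes were closer to the typical expressed gene. All 22 immediate-early genes were at 1 TPM or more in both libraries, but the list's median was 11.3 ± 2.80 TPM (percentile 85.8). Its highest members were the phosphatase genes Dusp1 (189 ± 60.9 TPM) and Dusp2 (167 ± 54.1 TPM), Klf6 (135 ± 3.15 TPM), the mRNA-destabilising Zfp36 (124 ± 24.6 TPM) and Junb (89.7 ± 25.2 TPM). Fosb (2.92 ± 1.92 TPM) and Egr3 (1.73 ± 0.0141 TPM) were lowest. The late response list had a median of 8.70 ± 0.728 TPM (percentile 61.7), with a wide span. Cd274, which encodes PD-L1 (224 ± 11.8 TPM), Socs3 (222 ± 51.7 TPM), Cd40 (219 ± 30.9 TPM), the itaconate-producing Acod1 (190 ± 6.90 TPM) and Clec4e (181 ± 41.2 TPM) were abundant. Fpr1 (0.560 ± 0.283 TPM) and Hp (0.375 ± 0.148 TPM) were under 1 TPM. When the mean of log2 values replaced the median, the percentile rose to 98.9 for the immediate-early list, above the random range, and to 94.2 for the late list. No unstimulated library was used, so these levels do not measure induction.

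Genes of the receptor pathway and of macrophage identity were well represented. Macrophage lineage genes had a median of 57.8 ± 0.552 TPM (percentile 100), led by Lyz2, the lipoprotein gene Apoe (503 ± 42.6 TPM) and the perforin-like Mpeg1 (472 ± 142 TPM). Lysosomal genes had a median of 133 ± 24.4 TPM (percentile 100), with 12 of 20 genes at 100 TPM or more in both libraries. TLR4 pathway genes had a median of 14.7 ± 2.95 TPM (percentile 95.8, and 96.9 to 99.5 under alternatives), led by the kinase gene Ikbke (392 ± 46.3 TPM), the co-receptor gene Cd14 (269 ± 76.4 TPM) and Irak2 (77.7 ± 21.7 TPM).

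Splicing factor genes had a median of 61.8 ± 13.8 TPM (percentile 100), with Rbm39 (341 ± 58.8 TPM), Srsf5 (320 ± 30.7 TPM) and Hnrnpa2b1 (253 ± 54.6 TPM) highest. Ribosomal protein genes had a median of 24.6 ± 1.36 TPM (percentile 100), none of 76 at 100 TPM or more in both libraries, and Rpl10 (65.2 ± 8.71 TPM), Rps9 (54.1 ± 10.6 TPM) and Fau (53.7 ± 9.97 TPM) highest. Nuclear-encoded respiratory chain genes had a median of 7.48 ± 1.05 TPM (percentile 47.7), with Atp5b (68.0 ± 23.9 TPM), Cox7c (28.4 ± 1.97 TPM) and Cox4i1 (27.2 ± 1.26 TPM) highest. The percentile was 77.7 with the second quantification and 85.1 after rescaling to protein-coding genes. Rescaling keeps the order of genes within a library, but its cutoff of 1 lets more low genes into the random lists. The 13 protein-coding genes of the mitochondrial genome had medians of 2701 and 10158 TPM in replicates 1 and 2. The list labelled small nuclear noncoding, of polymerase III and ribonucleoprotein RNAs, had a median of 659 ± 107 TPM. Nuclear long noncoding RNAs had one of 12.9 ± 0.205 TPM (percentile 87.9, but 98.1 after rescaling and 65.0 with the second quantification). Long noncoding RNAs described in stimulated macrophages had a median of 0.395 ± 0.134 TPM. Besides Mir155hg, only Snhg15 (11.2 ± 0.651 TPM), 1 predicted gene and 1 further member reached 1 TPM in both libraries. Replication-dependent histone genes had a median of 0.670 ± 0.297 TPM and proliferation genes one of 0.783 ± 0.0884 TPM. Medians under 1 TPM lie below all random lists by construction, since those held only genes at 1 TPM or more. Mki67, a marker of cycling cells, stood at 28.9 ± 3.61 TPM, Pcna at 19.4 ± 0.898 TPM, Tk1 at 8.18 ± 0.325 TPM and the linker histone gene Hist1h1c at 3.50 ± 0.877 TPM.

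Markers of other cell types were at or near 0. The list medians were 0.0025 TPM for T and NK cells, 0.030 TPM for B and plasma cells, 0.075 TPM for neutrophils, 0.273 TPM for dendritic cells and 0.0675 TPM for erythroid cells and megakaryocytes. They were 0 TPM for mast cells, basophils and eosinophils, 0.020 TPM for stromal and endothelial cells and 0.345 TPM for osteoclasts. All were under 1 TPM and so lay below every random list by construction. The highest single markers were Csf3r (40.6 ± 6.52 TPM), Bst2 (25.1 ± 9.64 TPM), which interferon also induces, Pf4 (19.9 ± 10.1 TPM), the osteoclast gene Acp5 (14.9 ± 1.70 TPM) and Cd4 (12.5 ± 4.58 TPM). The neutrophil gene S100a9 stood at 1.57 ± 0.0354 TPM, the endothelial gene Kdr at 3.25 ± 0.311 TPM, Kit at 1.96 ± 0.792 TPM and the B cell gene Cd79b at 0.295 ± 0.00707 TPM.

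**Figure D2:**
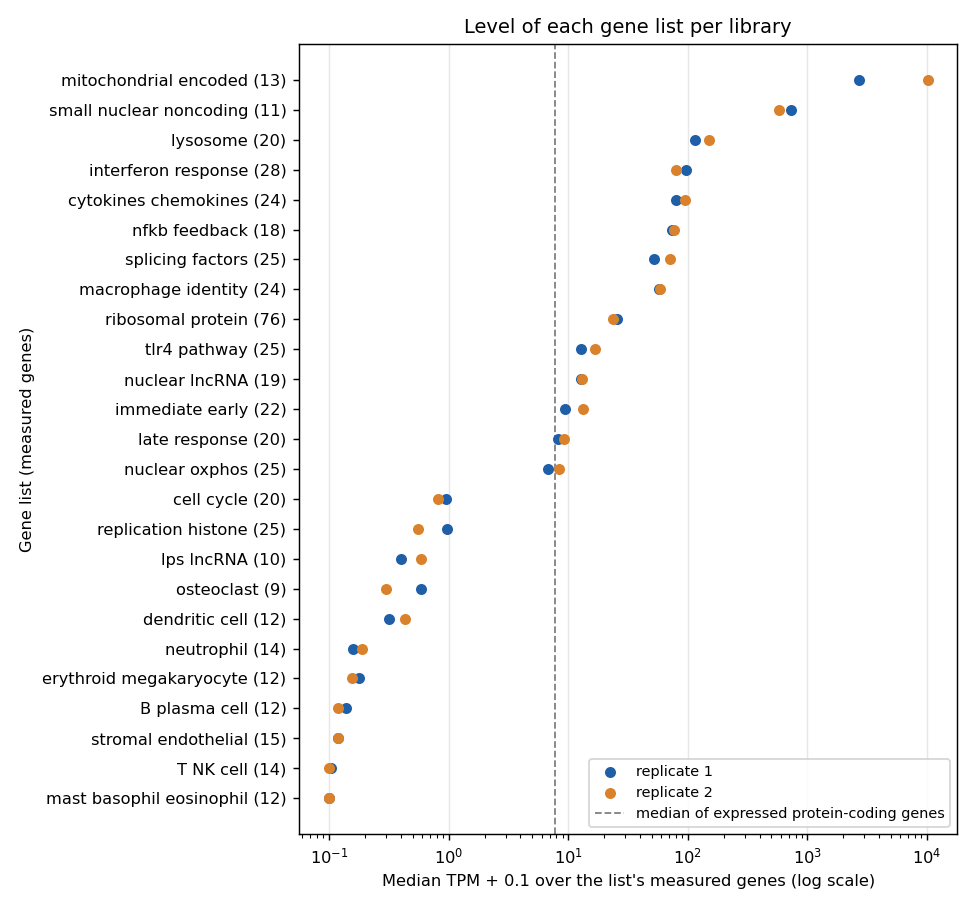
Median TPM + 0.1 of each gene list (horizontal axis, log scale) for each list (vertical axis, measured genes in brackets), 1 point per library. The dashed line marks the median of expressed protein-coding genes, 7.72 TPM before the offset of 0.1. The cytokine, interferon and NF-kB feedback lists lie between 73.5 and 96.9 TPM before the offset, and lists of other cell types under 1 TPM.

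Interferon response genes were lower in replicate 2, and mitochondrial RNA was higher. The interferon list had a median log2 ratio, replicate 2 over replicate 1, of -1.01 relative to other genes (2.01-fold lower), where random lists ranged from -0.20 to 0.10. All 27 members used lay below the median of other genes, of which Oasl1, named after its value was seen, did so by less than 0.01. By TMM-scaled counts, Rsad2 was 2.20-fold lower, Ccl5 2.06-fold and Cxcl11 3.87-fold, from 247 to 41 counts, while Gbp5 was 1.37-fold and Oasl2 1.19-fold lower. The cytokine and chemokine list had a median of -0.08 with 12 of 23 members lower, and of 0.0026 by TMM-scaled counts, both inside the random range, though Ccl4 was 2.21-fold lower. With the second quantification its median was -0.33, outside that range.

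Other response lists differed less. Immediate-early genes had a median of -0.33 (15 of 22 lower, and -0.20 by TMM-scaled counts) and late response genes of -0.29 (13 of 18 lower), all outside the random range. The NF-kB feedback list had a median of -0.22 (15 of 18 lower), inside that range, but outside it by TMM-scaled counts (-0.26), and -0.10 after removing the trend on GC content and length. Dusp1 was 2.06-fold and Dusp2 2.00-fold lower, and Fosb had a log2 ratio of 1.17.

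Mitochondrial genes had a median log2 ratio of 1.36 (2.57-fold higher, 12 of 13 members). Ribosomal protein genes had one of -0.46 with 70 of 76 lower, and histone genes one of -0.93 with 9 of 9 lower. The list of polymerase III and ribonucleoprotein RNAs had one of -1.22 with 8 of 9 lower. These lists all lay outside the random range. After removing the trend on GC content and length, the ribosomal protein median was -0.22 with 55 of 76 lower, still outside it. Lists inside it were lysosome (0.06), macrophage identity (-0.12), neutrophil (-0.06) and osteoclast (-0.07), and the TLR4 pathway (0.03) and splicing factors (-0.01), whose signs changed with the scaling. The nuclear-encoded respiratory chain list (-0.17) was inside it as well, but outside by TMM-scaled counts (-0.24) and with the second quantification (-0.32), and its sign turned when the trend on GC content and length was removed (0.06, inside). The dendritic cell list (-1.21, 4 genes, among them Bst2) and response-linked long noncoding RNAs (-0.68, 4 genes) lay outside it, but inside with the second quantification (-0.43 and -0.38). Proliferation genes (-0.46) and nuclear long noncoding RNAs (-0.28) lay outside it, but inside with a minimum of 5 TPM (-0.29 and -0.13), and proliferation genes also by TMM-scaled counts (-0.21) and with the second quantification (-0.14). The libraries also differed in starting RNA, 1 µg and 500 ng.

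In the first quantification, the largest single-gene ratios were those of small nucleolar RNAs, of mitochondrial genes and their nuclear copies, and of genes at 0 in 1 library. Zbed6 had 1963 counts in replicate 1 and 0 in replicate 2. The deposited interval of its TPM began at 9.60 in replicate 1 and ended at 1.75 in replicate 2. The predicted gene B430305J03Rik had 501 and 0 counts, with intervals beginning at 3.07 TPM in replicate 1 and ending at 0.397 TPM in replicate 2. It was at 0 TPM in both libraries with the second quantification. The small nucleolar RNA genes Snora73b and Snora73a were 13.5-fold and 8.78-fold lower and the predicted small nucleolar RNA Gm25776 8.60-fold lower. With the second quantification the differences were smaller, from 186 to 36.1 TPM for Snora73b, from 156 to 30.3 TPM for Snora73a and from 371 to 127 TPM for Gm25776. Gm37376 lies within the coordinates of Malat1, on the opposite strand, at 5801941 to 5802393 of chromosome 19. It had 0 and 1004 counts, with intervals ending at 2.10 TPM in replicate 1 and beginning at 91.2 TPM in replicate 2. The second quantification gave it 2232 and 4838 TPM, so its count of 0 in replicate 1 holds for the first only. The pseudogenes Gm28439 and Gm10222 on chromosome 1 were 165-fold and 4.17-fold higher, but with the second quantification Gm28439 had 698 and 4807 TPM and Gm10222 0 TPM in both libraries. The mitochondrial genes mt-Atp8 and mt-Atp6 were 4.38-fold and 3.98-fold higher.

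**Figure D3:**
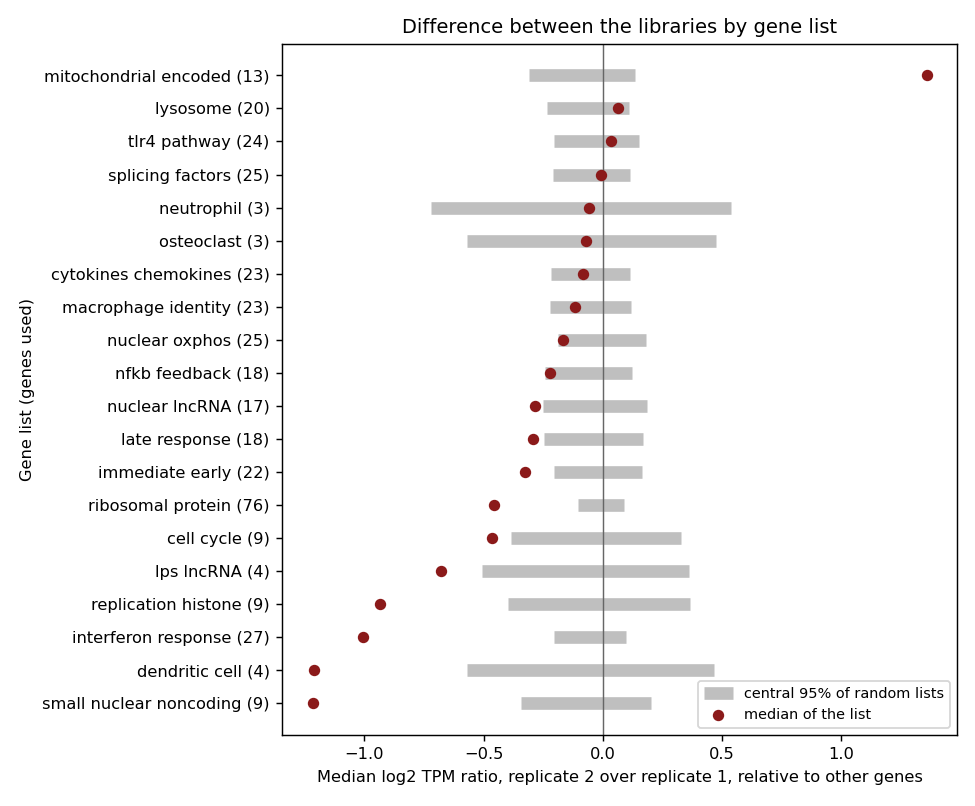
Median log2 ratio of TPM, replicate 2 over replicate 1, relative to other genes (horizontal axis) for each gene list (vertical axis, genes used in brackets). Points are list medians and grey bars the central 95% of 10000 random lists, with the interferon list at -1.01 and the mitochondrial list at 1.36.

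Across the 8560 expressed protein-coding genes, the libraries correlated with Pearson 0.971 and Spearman 0.966 on log2(TPM + 0.1), over genes, which are not independent replicates. After centring, 85.4% of genes differed by less than 1.5-fold. Beyond 2-fold were 251 genes, 49 higher and 202 lower in replicate 2. By TMM-scaled counts these were 26 and 162, and by the second quantification 282 and 224 of 9726 genes, so the excess of lower genes held for the first quantification only. The biological coefficient of variation was 0.210 over 13515 genes.

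Much of the TPM of splicing factor genes was assigned to retained-intron transcripts, and little of that of lysosomal genes. The share does not separate such transcripts from unspliced RNA, which nucleoplasmic RNA also holds. The splicing factor list had been written as one in which many genes have retained or detained introns. Random lists were matched on gene TPM, and not on the number of annotated retained-intron transcripts. The median share was 54.1% over 22 splicing factor genes (55.5% and 52.8% per library), above matched random lists with a median of 37.4% (percentile 99.7), and 14 of the 22 genes exceeded 50%. Srsf11 (86.0% ± 2.38) and Rbm5 (77.0% ± 1.01), both RNA-binding splicing regulators, and U2af1 (83.9% ± 8.14), which binds the 3' splice site, were highest. Lysosomal genes had a median of 12.7% over 14 genes (percentile 0.02), 21.6% with the second quantification (percentile 1.28) and 4.82% as a share of counts (percentile 0.08). Over all 5800 eligible genes the median was 34.8% ± 0.627, and 1543 genes (26.6%) exceeded 50%.

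Among response lists, late response genes had the highest share, 58.7% over only 5 genes (percentile 97.0, and 99.2 in replicate 1 alone). Interferon genes had 48.2% (16 genes, percentile 92.1), NF-kB feedback genes 37.5%, immediate-early genes 26.7% and cytokine genes 22.2% (8 genes, percentile 6.43), all inside the random range. The TLR4 pathway (39.5%), macrophage identity (25.9%), respiratory chain (37.6%) and proliferation (26.9%) lists were inside it as well, though the macrophage identity list was outside with the second quantification (18.4%, percentile 1.65). The proliferation list, with 6 eligible genes, had 38.8% in replicate 1 and 17.6% in replicate 2. Ribosomal protein genes had 27.5% over 61 genes (percentile 0.63), but stood at percentile 90.7 when the share was taken of counts and at 8.38 with the second quantification. As a share of counts, the median rose to 61.5% for splicing factors (percentile 100) and 28.4% for macrophage identity (percentile 64.4). It was lower, at 36.1% for late response, 29.8% for interferon, 22.2% for NF-kB feedback, 14.2% for immediate-early, 20.3% for TLR4 pathway, 21.2% for respiratory chain and 13.2% for proliferation genes, all inside the random range. Introns without an annotated transcript had no entry of their own in either quantification.

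**Figure D4:**
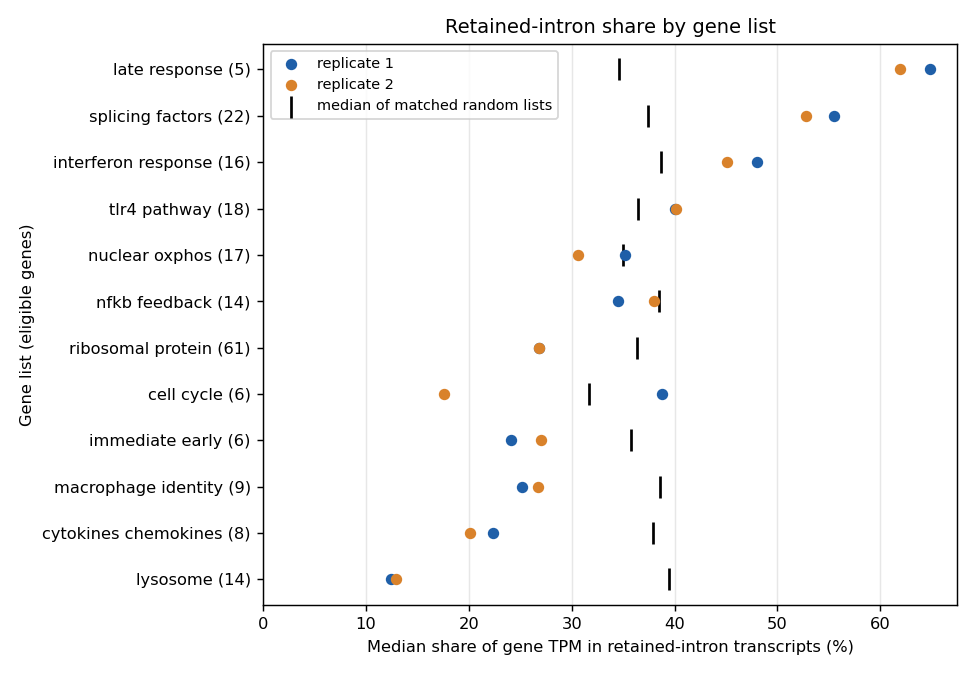
Median share of gene TPM in retained-intron transcripts (%, horizontal axis) for each gene list (vertical axis, eligible genes in brackets), 1 point per library, with a tick at the median of matched random lists. Splicing factors stand at 55.5% and 52.8% and lysosomal genes at 12.4% and 12.9%.

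The second quantification gave similar gene levels from more reads. It assigned 1.36 times as many counts as the first in replicate 1 and 1.85 times as many in replicate 2. Over protein-coding genes at 1 TPM or more in both quantifications, Spearman across genes was 0.920 in replicate 1 (8449 genes) and 0.907 in replicate 2 (8822 genes). After centring, 73.8% and 73.7% of genes lay within 1.5-fold. The cytokine, interferon and NF-kB feedback lists stayed at percentile 100, and all 28 interferon genes were lower in replicate 2.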

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

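A signal appeared in a feature that none of the comparisons used, the genome of the phage phiX, which is added to many sequencing runs as a control. It held 1.135% of estimated counts in replicate 1 (257300 counts, Wilson 95% interval 1.13% to 1.14%) and 0.304% in replicate 2 (45368 counts, 0.301% to 0.306%), far above the 3 counts that a count of 0 allows. The ERCC spike-in entries had 0 counts in both libraries.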

How the results depend on the processing

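Of 374 values under alternatives, 143 were for main results, and 123 of these stayed within the replicate spread, on their side of the random range or, for counts of genes, within 1.5 times the main count. For shares of RNA classes, each library alone lies within the SD of their mean by construction, so these values could not move. For list percentiles the spread was the SD of the single-library percentiles, so single-library values there had little room to move. The mitochondrial share was 4.92% in replicate 1 and 12.1% in replicate 2. The cytokine, interferon and NF-kB feedback lists stayed at percentile 100 under all alternatives run for their level. The interferon, mitochondrial, ribosomal protein and histone differences, and that of polymerase III and ribonucleoprotein RNAs, kept their direction. They stayed outside the random range under each alternative run for them. No list difference outside the random range changed sign under an alternative. Inside it, the median of cytokines became 0.0026 with TMM-scaled counts, that of the TLR4 pathway -0.048 with these and -0.18 with the second quantification, and that of splicing factors 0.0083 with TMM-scaled counts and 0.04 with a pseudocount of 1. That of the respiratory chain became 0.06 with the GC and length correction. The GC and length correction and the other counts of genes beyond 2-fold were chosen after seeing the data. At 5 TPM, 5684 genes were detected, against 10692 at 1 TPM, 12502 at 0.5 TPM, 13440 at 10 counts and 15315 with the second quantification. The coefficient of variation was 0.235 with no count filter and 0.308 with the second quantification, where Pearson was 0.956, 506 genes lay beyond 2-fold (282 higher and 224 lower in replicate 2, against 49 and 202) and the long noncoding share was 18.4%. As shares of TPM, which divide counts by length, small noncoding RNA held 58.7%, long noncoding RNA 5.01% and protein-coding genes 19.8%. The percentile of the immediate-early list was 96.9 after rescaling to protein-coding genes, 60.9 with the second quantification, 98.9 with means of log2 values and 91.4 against all genes. For the late list it was 89.1, 87.9, 94.2 and 73.6. Protein-coding genes held 17.8% and 21.8% of TPM, so a cutoff of 1 after rescaling admitted genes under 1 deposited TPM. Rescaling keeps the order of genes within a library, so the higher percentiles after it reflect a reference set with more low genes. The NF-kB feedback difference moved outside the random range with TMM-scaled counts (-0.26), as did that of cytokines with the second quantification (-0.33). The respiratory chain difference moved outside it and those of proliferation genes, dendritic cells and both long noncoding lists inside it under the alternatives given with their values. The late list's retained-intron share was 61.9% to 64.9% in single libraries. Apart from the shares of TPM and the percentiles after rescaling, the cause was not tested for these. No paired analysis was possible because there is 1 group, and the coefficient of variation and replicate differences need both libraries. At 24 counts per TPM in replicate 2, levels under 1 TPM are poorly resolved.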

Other observations

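The genes in this paragraph and the next lie outside the gene lists and were chosen after their values were seen. Abundant transcripts outside the lists came from genes of several kinds. The class I antigen-presenting gene H2-D1 stood at 776 ± 35.3 TPM (SD, n = 2), the transcription factor gene Zeb2 at 740 ± 201 TPM, the hyaluronan receptor gene Cd44 at 679 ± 152 TPM and the adhesion molecule gene Icam1 at 511 ± 126 TPM. The deadenylation-related nocturnin gene Noct stood at 364 ± 51.4 TPM, the osteopontin gene Spp1 at 540 ± 51.1 TPM and the ferritin gene Fth1 at 473 ± 34.4 TPM. Fchsd2 (672 ± 260 TPM), Zc3h7a (563 ± 179 TPM), the actin gene Actb (554 ± 45.1 TPM), the selenoprotein gene Selenop (383 ± 186 TPM) and the RNA helicase gene Ddx5 (347 ± 46.8 TPM) were also among them. Parp14 (465 ± 3.86 TPM) and Ifi203 (455 ± 12.9 TPM), both known interferon-inducible genes, were at the level of Gbp5.

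Some of the genes outside the lists had most of their TPM assigned to retained-intron transcripts in the first quantification. Of 192 eligible genes outside the lists with 100 TPM or more, 10 had a share of 75% or more in both libraries. Lilrb4a had 97.4% and 97.7%, the inhibitory receptor gene Pirb 81.5% ± 3.52, the activation marker gene Cd83 80.6% ± 2.01, and Ptprc, which encodes CD45, 79.7% ± 0.249. With the second quantification, Ptprc had 48.3% and 40.8%, and Pirb 87.3% and 79.1%. The kinase gene Camk2d had 83.8% ± 0.280 and the ceramide synthase gene Cers6 79.2% ± 0.559. The other members were Ddhd1 (81.4% ± 4.70), Anxa7 (81.1% ± 0.214), Zc3h7a (78.5% ± 1.11) and Sav1 (77.4% ± 2.29).

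The tests of the interferon and mitochondrial patterns, and that of single-exon genes, were chosen only after the results were seen, while the other tests on the second quantification were set beforehand. Among 5931 protein-coding genes with a mean of 200 counts or more, 71 were beyond 2-fold lower in replicate 2 by TMM-scaled counts and 9 higher, and 11 of the 71 were members of the interferon list. The lower genes outside the lists included the immunity-related GTPase genes Tgtp2 (3.69-fold), Ifi47 (2.87-fold), Igtp (2.77-fold) and Iigp1 (2.59-fold), the immunoproteasome gene Psmb8 (3.44-fold), the transcription factor gene Batf2 (3.07-fold), the signalling inhibitor gene Socs1 (2.58-fold) and the chemokine gene Ccl12 (2.52-fold). Calhm6 (2.72-fold) and Themis2 (2.56-fold) were lower as well, and so was Exoc3l4, while Srp54b was 3.25-fold lower by counts but higher by TPM as deposited. These genes outside the lists were chosen after their values were seen.

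The lower interferon list in replicate 2 is not accounted for by scaling or quantification, since its median was -1.01 with TMM-scaled counts and -1.16 with the second quantification. After removing the trend on GC content and length, which held 9.08% of the variance of the ratios, it was -0.94 with 26 of 27 genes lower. A weaker response of all lipid A genes was judged by the cytokine list. The bound, set after seeing the data, was 0.5 of the interferon list's log2 ratio. The cytokine median was -0.0817 against -0.50, and -0.33 against -0.58 with the second quantification, so a uniform shift of that size was not seen. Its members went both ways, with 12 of 23 lower and 11 higher. The 5 with the highest TPM were 1.29-fold to 2.21-fold lower by TMM-scaled counts. The immediate-early (-0.33), late (-0.29) and NF-kB feedback (-0.22) lists were lower as well. A weaker response of unequal size across the genes stays open. A difference in the strength or timing of the interferon arm between the cultures is a hypothesis that was not tested, and it cannot be separated from the starting RNA of 1 µg and 500 ng.

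Mitochondrial RNA was 2.57-fold higher in replicate 2 by the list's median. More cytoplasmic mRNA in that library would raise ribosomal protein and nuclear-encoded respiratory chain genes, but after removing the trend on GC content and length their medians were -0.22, below all random lists, and 0.06, inside the random range. The bound set for this test, both medians at 0 or lower, was missed by the respiratory chain list, so the argument rests on the ribosomal protein list, a choice made after both values were seen. Reads shared with nuclear copies of mitochondrial DNA would leave the summed share of mitochondrial genes and pseudogenes equal, but it was 6.86% and 16.0%, a log2 ratio of 1.22. Mitochondria carried along in the fractionation, and the amount of starting RNA, stay open and were not tested.

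The second quantification counted more reads in protein-coding genes, with a median log2 ratio over the first of 0.46 in replicate 1 and 0.84 in replicate 2 over 8260 genes. Genes with 10 or more exons exceeded the 89 single-exon genes by 0.33 (bootstrap 95% interval 0.28 to 0.35) and 0.23 (0.18 to 0.28), which argues against a constant difference for all genes. Reads reaching from exons into introns would give such a difference and may contribute. The difference does not show that they do, since the ratio need not track intron content, as splicing factors show below. Single-exon genes still had ratios of 0.15 and 0.62, so such reads could cover at most part of the excess, whose cause stays open. Of the 5 response lists, 0 exceeded lists matched on exon number in both libraries, which had been set beforehand as a bound against more unspliced RNA in response genes. It decides nothing, since splicing factors, whose retained-intron share was high (54.1%, percentile 99.7), lay at percentile 0 of this ratio in both libraries, so the ratio need not track intron content and the question stays open.

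Genes of chromosome Y differed between the quantifications. In the first, 2 of 1570 had any counts, 18 in total in each library, and Kdm5d, Uty, Ddx3y and Eif2s3y had 0. In the second, all 1570 genes together had 23152 and 12628 counts, of which 3.70% and 10.1% were in retained-intron transcripts. There, these 4 genes, chosen after their values were seen, had 1145 and 1689 counts, of which 74.8% and 75.8% were in retained-intron transcripts. Xist had 179356 and 122724 counts in the first quantification.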
